A study of Homo sapiens with 6 samples.

How the data were processed

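Gene expression was measured in 6 cultures of BL2 cells, an established human Burkitt lymphoma line, after electroporation with scrambled siRNA or with a pool of 4 siRNAs against LEF1. Each group had 3 biological replicates, per the series' design text, and each of 3 labelled batches held 1 array of each group. Total RNA was made into biotinylated cRNA with a 3' in vitro transcription kit, per the labels' protocols, so the arrays read mainly the 3' ends of transcripts.

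The deposited values were 1 log2 expression value per probe set and array for 54675 probe sets of the HG-U133 Plus 2.0 array. The method of background correction, normalization and summarisation was not given in the sources used here. That the deposited values are on a log2 scale was read from their range of 5.45 to 15.0. Array medians ran from 6.89 to 6.96, and the arrays' sorted values differed by up to 0.298, so the distributions were close but not forced to be equal. Values near the lower end hold mostly background, which compresses log2 differences of weakly expressed genes. The number of arrays limits the precision.

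The 62 Affymetrix control probe sets were kept out of the main test, which left 54613. Gene names came from the platform's annotation, checked against the RefSeq genes of GRCh38.p14, which changed 0 symbols. Of the tested probe sets, 41091 named 1 gene, 1801 named several and 11721 named none here. Names were used only from probe sets with 1 gene, which covered 19777 genes.

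Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the data.table package, version 1.17.8. P-values are two-sided with Benjamini-Hochberg adjustment over the 54613 probe sets and a threshold of 0.05. A fit without block and a fit with batch as block were both fixed before the data were examined, as were the gene lists and the rule for named genes. The batch label pairs 1 array of each group. Deviations from the group means correlated at 0.477, 0.493 and 0.621 between arrays of 1 batch. The 6 pairs of a LEF1 siRNA and a scrambled siRNA array from different batches correlated below 0. That adds no further evidence of pairing, since deviations sum to 0 within a group, which forces these pairs below 0 on average. Correlations here are across probe sets, which are not independent replicates. The fit without block had 4 residual degrees of freedom and 4.07 prior ones. With batch as block there were 2 residual and 12.0 prior degrees of freedom, so that fit leans on the spread shared across probe sets.

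The 29 gene lists held 688 different genes, of which 622 were measured. For list tests the brightest probe set stood for each gene. Camera was run with a preset inter-gene correlation of 0.01 and again with an estimated correlation, beside fry. With an estimated correlation camera uses only the residual degrees of freedom. The lack of a call there does not show that a list was unchanged. Single control measures were compared by exact permutation of the 6 arrays, where 3 against 3 cannot give a p below 0.1, and by exact sign changes of the 3 batch differences, which cannot give a p below 0.25. Named genes were LEF1 at every probe set, and in each fit the 12 genes with the largest rise and the 12 with the largest fall. These had to pass the threshold, change the same way in 3 batches and lie above the median level. Where several probe sets of a gene met this, the most changed one was named. From each list, up to 4 members past the threshold with the smallest p were named, or up to 2 as values where none passed.

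Both fits were tested on simulated data with the comparison's own means and spread for 54613 probe sets, of which 100 were changed by 0.5 and 100 by 1 on the log2 scale. The fit without block recovered 46% of the smaller and 96% of the larger changes. The fit with batch as block recovered 100% of each, with 12 false calls among 212. In a separate simulation over 19777 genes, 1 list lowered by 0.15 was found by camera in both fits, and 0 of 28 other lists were called. Simulated noise was independent between probe sets, so this does not show how often correlated genes give false list calls. In the data the estimated correlations within lists ran from -0.024 to 0.92 with batch as block. The simulated spread was drawn from the fit with batch as block, which may favour that fit.

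Alternatives covered the block, other normalizations, dim probe sets, 1 probe set per gene, eBayes settings, array weights, thresholds, list tests and leaving out each array or batch. Cyclic loess normalization and scaling to the poly-A spike-ins were added after the data were seen. The pseudocount planned for linear values did not apply to log2 values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.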

Results

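The series holds 6 expression arrays of BL2 cells, 3 after scrambled siRNA and 3 after a pool of 4 siRNAs against LEF1. LEF1 encodes a DNA-binding partner of beta-catenin in Wnt signalling. The comparison asks which transcripts differ in Burkitt lymphoma cells once LEF1 is lowered. Values are log2 expression, and errors are SDs over 3 arrays unless named otherwise.

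LEF1 fell in all 3 batches. Its brightest probe set went from 11.04 ± 0.43 (SD, n = 3) with scrambled siRNA to 8.32 ± 0.30 with LEF1 siRNA, which left 15.2% of the signal. The log2 difference of -2.71 had a limma adjusted p of 0.0213 without block and 7.46e-11 with batch as block. A probe set of middle brightness fell from 8.45 ± 0.19 to 6.61 ± 0.09, below the median of 6.91 of all probe sets, so that at most 28.0% was left (limma adjusted p = 0.00418 without block). The dimmest LEF1 probe set, at 7.58 ± 0.07 with scrambled siRNA, differed by -0.29 and kept 81.5% of its signal. That difference passed only with batch as block (limma adjusted p = 0.00695, against 0.284 without). Without block, the brightest probe set no longer passed when scrambled siRNA replicate 1 or 3, LEF1 siRNA replicate 1 or 2, or both arrays of batch 1 or 2 were left out, at differences between -2.83 and -2.51.

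**Figure D1:**
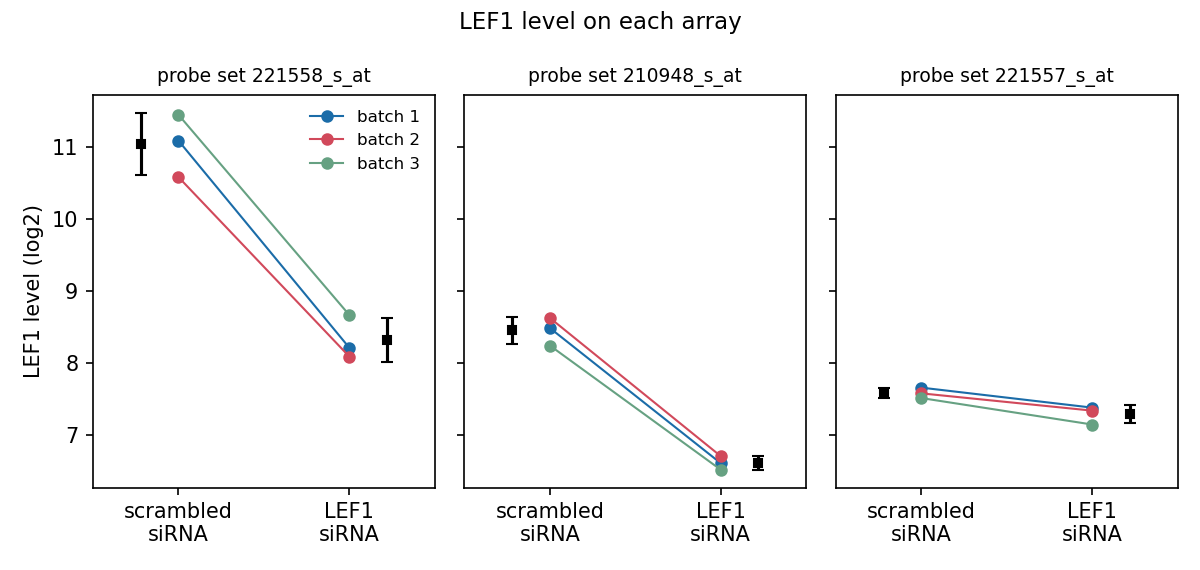
LEF1 level (log2) on each of the 6 arrays for its 3 probe sets, with lines joining the arrays of a batch and squares with bars giving the group mean and SD. The brightest probe set falls from a mean of 11.04 to 8.32, and the dimmest from 7.58 to 7.29.

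Without block, 10 probe sets passed, 6 higher and 4 lower with LEF1 siRNA. TARS3, a threonyl-tRNA synthetase gene, rose 2.16-fold, from 7.15 ± 0.10 to 8.26 ± 0.04. SATB1, a chromatin organiser of lymphocytes, rose by 0.81 on the log2 scale, and NCKAP1L, a haematopoietic regulator of the actin skeleton, by 0.80. ARL6IP5 rose by 0.74 and SESN3, a stress-response gene of the sestrin family, by 0.72. PSAT1, an enzyme of serine synthesis, fell by 0.65 and the phosphatase gene CTDSPL fell by 0.60. The remaining calls were LEF1 at 2 probe sets and 1 probe set with no gene name here. Apart from LEF1, no further probe set of these named genes passed without block. The brightest ones of NCKAP1L and PSAT1 differed by 0.30 and -0.43 (limma adjusted p = 0.216 and 0.0837). Poly-A spike-in scaling, described below, gave 11 probe sets, of which 3 were among the 10, and SATB1, NCKAP1L, ARL6IP5, SESN3, PSAT1 and CTDSPL did not (limma adjusted p = 0.583, 0.605, 0.876, 0.876, 0.0978 and 0.211). Leaving out LEF1 siRNA replicate 2 gave 0 calls, and leaving out both arrays of batch 1 or of batch 2 also gave 0.

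With batch as block, 3328 probe sets passed, which named 2393 genes, and they included all 10 above. Their median size was 1.22-fold, and 81 reached 1.5-fold. CCR7, a lymph-node homing receptor, rose 2.19-fold, from 7.89 ± 0.39 to 9.02 ± 0.60. The protease gene CTSS rose by 1.11 at 1 probe set and by 0.23 at another of its 3, the survival gene BCL2A1 by 0.99 and the activation marker CD83 by 0.85. The histone genes H2BC12 and H2AC6 rose by 0.98 and 0.85, MARCKS by 0.89, ATP2B1 by 0.83 and KLHL14 by 0.83. IGLL1, a surrogate light chain gene of B cell precursors, fell by 1.19, from a mean of 10.19 ± 0.35 with scrambled siRNA. The transcription factor gene ATF5 fell by 0.90, MAN1A1 by 0.71, the histone variant gene H2AZ2 by 0.70 and ANKRD36BP2 by 0.68. SEPTIN9 fell by 0.66, DNTT by 0.62, ALDH5A1 by 0.60 and CDC27, a subunit of the anaphase-promoting complex, by 0.58. CCR7, CTSS, BCL2A1, CD83 and IGLL1 did not pass without block (limma adjusted p = 0.279, 0.207, 0.466, 0.809 and 0.107). Other probe sets of some of these genes did not pass. The brightest ones differed by 0.18 for CTSS, 0.05 for TARS3, -0.13 for SEPTIN9, -0.16 for CDC27 and -0.20 for ALDH5A1. Further ones differed by 0.22 for MARCKS, 0.21 and 0.04 for KLHL14, -0.07 and -0.08 for ATF5, and -0.05 for H2AZ2. Dimmer ones of SESN3, CTDSPL, SATB1, DNTT and ANKRD36BP2 did not pass either. The brightest probe sets of MAN1A1, ATF5 and NCKAP1L passed with smaller differences, of -0.31, -0.50 and 0.30.

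**Figure D2:**
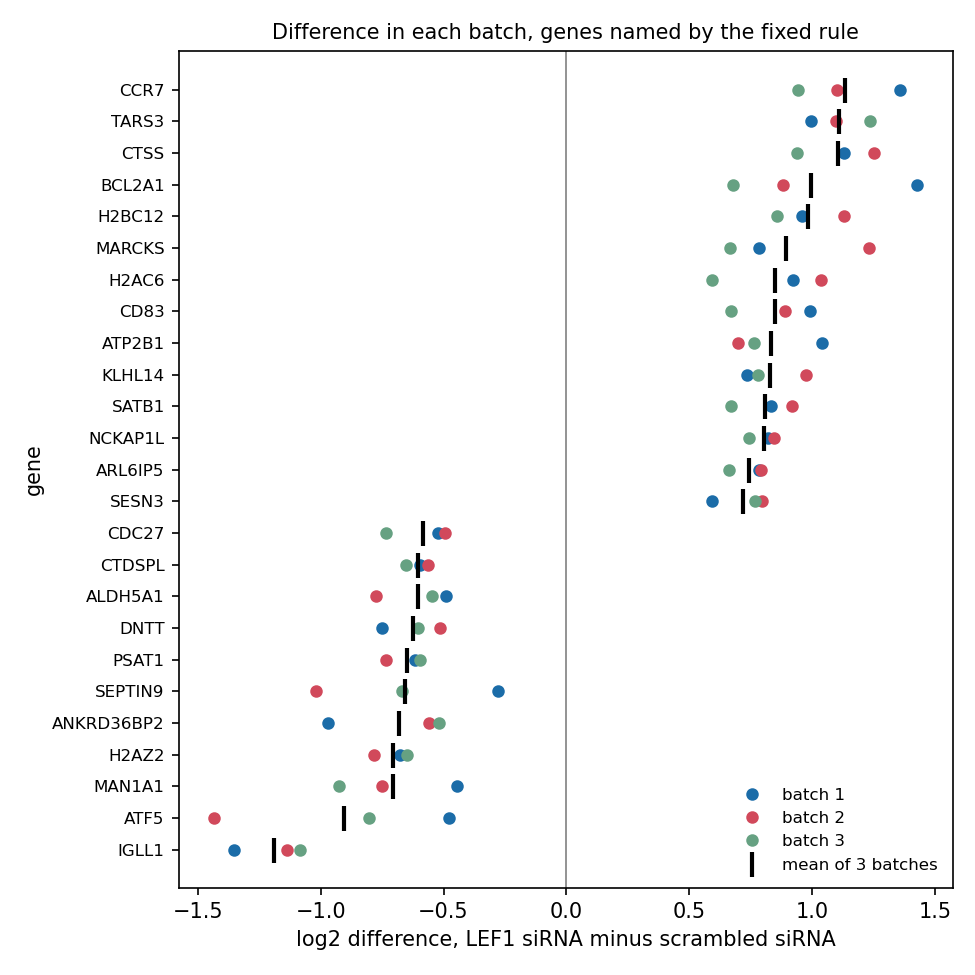
Log2 difference (LEF1 siRNA minus scrambled siRNA, x axis) of the genes named by the fixed rule other than LEF1, with a point per batch and a bar at the mean. Each gene lies on 1 side of 0 in all 3 batches, as the rule requires, from IGLL1 at -1.19 to CCR7 at 1.13.

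Of these 3328 probe sets, 2501 were higher and 827 lower, so 75.2% were higher. That split moved with the scaling, to 66.4% higher after setting equal medians, 60.1% after cyclic loess and 56.1% after quantile normalization. Scaling to the poly-A spike-ins moved the median of all probe sets to -0.13 and called 13508 of 54613, of which 6.48% were higher. It lowers the difference of every probe set by the same 0.14, so falls counted per list under it include this shift. Named genes and list members called on the deposited scale kept their direction under these scalings, but counts per list did not, so counts and means below are relative to the bulk of probe sets on the deposited scale. Leaving out batch 2 lowered the count to 1407.

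Many cell division genes were lower with LEF1 siRNA in the fit with batch as block. Of 25 measured genes of the G2/M and mitosis list, 13 fell and 0 rose with batch as block, and 16 fell when adjusted over the list alone. CCNA2, the cyclin A2 gene, fell by 0.57, CDC20 by 0.36, the mitotic kinase gene PLK1 by 0.33 and the checkpoint kinase gene BUB1 by 0.30. The list's mean change was -0.21, and -0.18, -0.28 and -0.16 in batches 1, 2 and 3. Of 27 genes of the G1/S and DNA replication list, 9 fell and 20 fell when adjusted over the list alone. CDC45 fell by 0.40, RRM2, a ribonucleotide reductase subunit, by 0.35, MCM3 by 0.32 and MCM7 by 0.30, and the batch means were -0.14, -0.30 and -0.13. Camera called both lists lower in both fits (adjusted p = 1.96e-16 and 1.42e-14 with batch as block), but neither with an estimated correlation (adjusted p = 0.618 for each). The estimated correlations were 0.38 and 0.47, far above the preset of 0.01. That version has only 2 residual degrees of freedom with batch as block. With so few, the lack of a call there does not show that these lists were unchanged, and the camera calls rest on the preset correlation. The Wnt target list had the same adjusted p of 0.618. Such ties can come from the Benjamini-Hochberg adjustment and rank no list.

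The early B cell precursor list and the unfolded protein and integrated stress list were also called lower. In the precursor list 4 of 11 genes fell and 0 rose, also when adjusted over the list alone. Besides IGLL1 and DNTT these were RAG2, by 0.43, and IL7R, by 0.34. RAG2 read only 7.01 with scrambled siRNA and 6.58 with LEF1 siRNA, around the median of 6.91 of all probe sets. Its values may thus hold mostly background. The list's batch means were -0.32, -0.20 and -0.26 (camera adjusted p = 1.98e-06 with batch as block; adjusted p = 0.618 with an estimated correlation). In the unfolded protein and integrated stress list 7 of 24 genes fell and 1 rose, or 9 and 3 when adjusted over the list alone. PSAT1 at its brightest probe set fell by 0.43, the asparagine synthetase gene ASNS by 0.37, the transcription factor gene ATF4 by 0.36 and PHGDH by 0.34. The chaperone gene DNAJB9 rose by 0.22 (camera adjusted p = 0.000175; adjusted p = 0.618 with an estimated correlation), but passed under none of the 4 other scalings (lowest limma adjusted p = 0.0740, with equal medians).

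Among MYC targets, 2 of 26 genes fell, TFRC by 0.32 and SHMT2 by 0.27, and adjusted over the list alone 6 fell and 1 rose. The list was called lower by camera (adjusted p = 9.28e-05, and adjusted p = 0.618 with an estimated correlation), and 17 of its genes fell under poly-A spike-in scaling. Of 24 cytosolic ribosomal protein genes none passed, also when adjusted over the list alone. RPS6 differed by -0.10 and RPS14 by -0.09. Camera called that list lower (adjusted p = 0.0449, and adjusted p = 0.846 with an estimated correlation), yet its batch means were 0.07, 0.02 and -0.18, its mean turned positive under quantile normalization, and the call was lost there (adjusted p = 0.0928) and under poly-A spike-in scaling (0.0674). Among random lists matched on level, a test chosen after the results were seen, its mean of -0.029 lay at percentile 76.0, so it was not lower than other genes of its level. In the germinal-centre and Burkitt identity list 4 of 24 genes fell and 3 rose, or 5 and 3 when adjusted over the list alone. CCND3 fell by 0.47, MME, which encodes CD10, by 0.43 and MEF2C by 0.41, while LMO2 rose by 0.55 (camera adjusted p = 0.034, lower; adjusted p = 0.618 with an estimated correlation). That call was lost without block (adjusted p = 0.0692), under quantile normalization (adjusted p = 0.106), equal medians (0.0538), cyclic loess (0.0962) and poly-A spike-in scaling (0.0928), and without batch 2 (0.0867) or 3 (0.0514). Of its genes 1 rose and 11 fell under poly-A spike-in scaling.

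The MHC antigen presentation list and the NF-kappaB target list were called higher. Of 23 measured genes of the MHC class I and class II list, 9 rose and 1 fell, or 11 and 1 when adjusted over the list alone. The 9 were CIITA and class II genes, among them HLA-DQA1 by 0.65, HLA-DQB1 by 0.60, HLA-DMB by 0.59 and HLA-DOB by 0.37, while the proteasome gene PSMB8 fell by 0.22. CIITA passed under none of the 4 other scalings (lowest limma adjusted p = 0.0684, with equal medians). The list's batch means were 0.34, 0.16 and 0.12, and its mean went from 0.20 to 0.065 under poly-A spike-in scaling (camera adjusted p = 1.07e-05; adjusted p = 0.618 with an estimated correlation). Of 22 NF-kappaB targets 5 rose, or 6 when adjusted over the list alone, and 0 fell. They included CCR7, CD83, BCL2A1 and CD40, which rose by 0.39, and the batch means were 0.33, 0.17 and 0.16. Camera called this list with batch as block (adjusted p = 0.00079; adjusted p = 0.618 with an estimated correlation) and not without (adjusted p = 0.108). Under poly-A spike-in scaling 4 targets rose and 2 fell, against 5 and 2 antigen presentation genes.

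In the lymphocyte migration and adhesion list 7 of 24 genes rose and 0 fell, or 8 adjusted over the list alone. DOCK8 rose by 0.47, the sphingosine phosphate receptor gene S1PR1 by 0.42 and ITGB1 by 0.38 (camera adjusted p = 0.0102; adjusted p = 0.618 with an estimated correlation). In the TGF-beta and BMP list 7 of 25 genes rose and 1 fell, or 8 and 1 adjusted over the list alone. SKIL rose by 0.65, ID1 by 0.63, ID4 by 0.54 and the receptor gene BMPR2 by 0.54 (camera adjusted p = 0.0102; adjusted p = 0.641 with an estimated correlation). Of 19 genes of cholesterol and fatty acid synthesis 5 rose, or 6 adjusted over the list alone, with MSMO1 at 0.41 and HMGCS1 at 0.39 (camera adjusted p = 0.0233; adjusted p = 0.641 with an estimated correlation). Among 24 apoptosis regulators 9 rose and 2 fell, or 13 and 3 adjusted over the list alone. The survival gene BCL2A1, also in the NF-kappaB list, rose by 0.99, CASP8 by 0.36 and BMF by 0.29, while HRK fell by 0.38 (camera adjusted p = 0.0283; adjusted p = 0.618 with an estimated correlation). This list mixes genes that prevent and genes that promote cell death, so its call gives no direction of apoptosis. The TGF-beta and apoptosis lists were not called without block (adjusted p = 0.0747 and 0.188). The apoptosis and cholesterol calls with batch as block were lost when dim probe sets were left out (adjusted p = 0.122 and 0.118) or batch 1 was (0.111 and 0.449), and the cholesterol call with the most variable probe set per gene (0.588). Without block, leaving out batch 1 ended the cholesterol and migration calls (0.300 and 0.0986). Under poly-A spike-in scaling the mean changes turned to -0.028 for the cholesterol, -0.0068 for the apoptosis and -0.00097 for the TGF-beta list, though camera, which compares with other genes, still called these higher. Then 4 migration genes rose and 4 fell, as in the TGF-beta list, against 3 and 5 apoptosis and 2 and 3 cholesterol genes, and BMF did not pass (limma adjusted p = 0.0894).

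**Figure D3:**
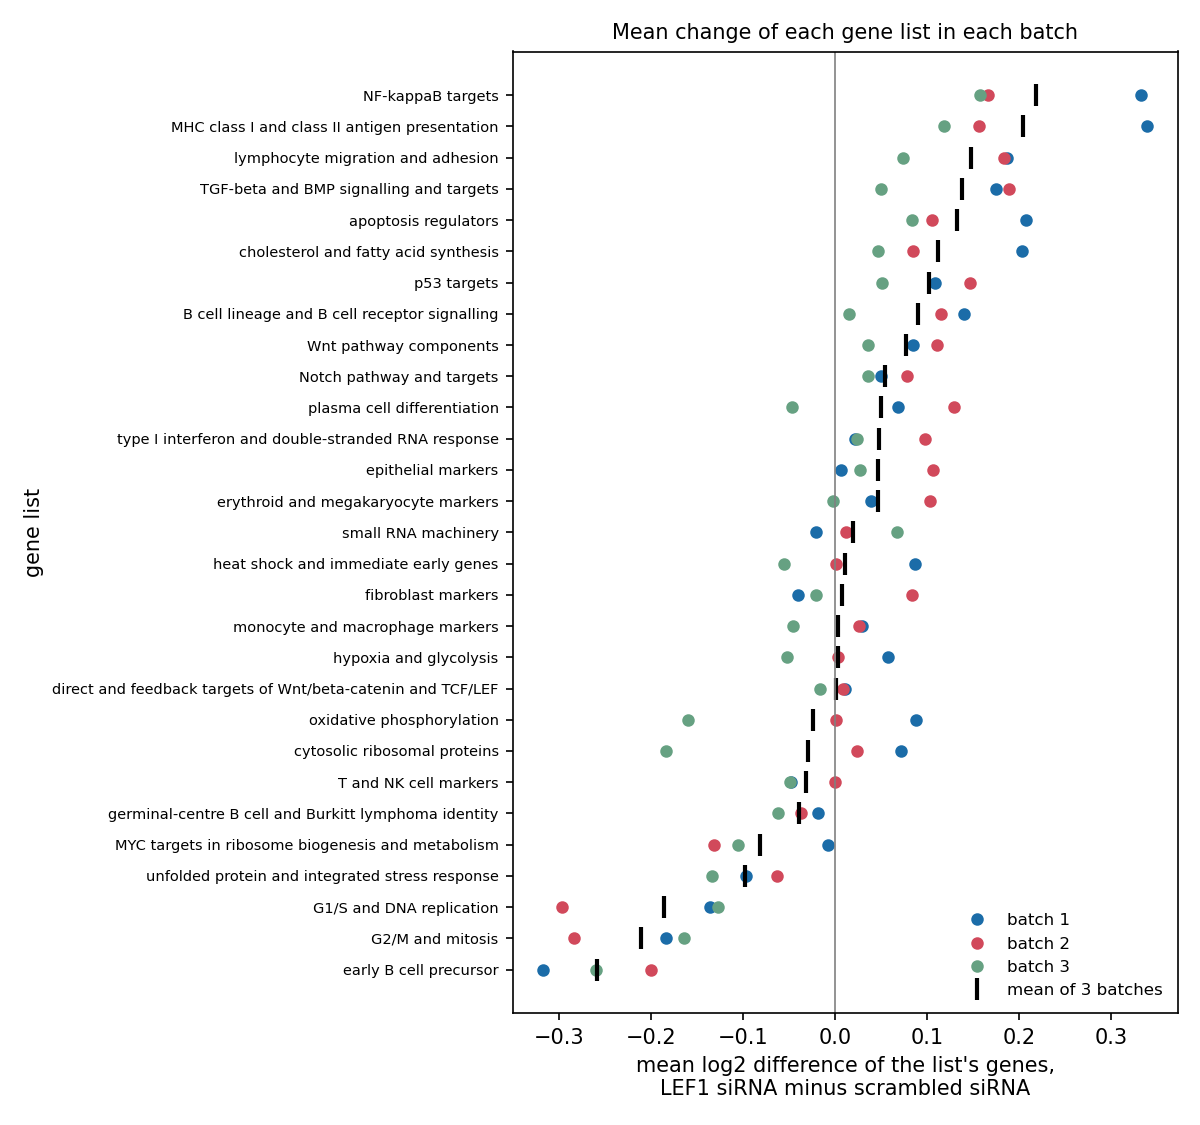
Mean log2 difference of the genes of each of 29 lists (x axis, LEF1 siRNA minus scrambled siRNA), with a point per batch and a bar at the mean. The means run from -0.26 for early B cell precursor genes to 0.22 for NF-kappaB targets, on the deposited scale.

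Targets of Wnt signalling were not called as a group by camera in either fit. With batch as block they passed the mixed test of fry, described below (fry mixed adjusted p = 0.0261). Of 30 measured targets of beta-catenin and TCF/LEF, 2 rose and 2 fell, also when adjusted over the list alone. Their median level was 7.08, near the median of 6.91 of all probe sets. Changes of weakly expressed genes are compressed, so the lack of a camera call does not show that the targets were unchanged. Under poly-A spike-in scaling, which lowers the difference of every probe set, 1 rose and 9 fell. PPARD rose by 0.34. ID2 passed at 0.38, but its batch differences were 0.64, 0.54 and -0.06 and it did not pass with equal medians (limma adjusted p = 0.0517) or under poly-A spike-in scaling (0.0612), while the survivin gene BIRC5 fell by 0.36 and VEGFA fell by 0.27. The list's batch means were 0.01, 0.01 and -0.02 (camera adjusted p = 0.294). Of 31 Wnt pathway components 6 rose, or 7 adjusted over the list alone, among them WNT5A by 0.39, APC by 0.38, RYK by 0.37 and FZD2 by 0.27 (camera adjusted p = 0.175). Under poly-A spike-in scaling 3 components rose and 5 fell, and FZD2 did not pass (limma adjusted p = 0.121).

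Other lists were not called by camera in either fit. In the B cell lineage list 5 of 25 genes rose and 1 fell, or 8 and 2 adjusted over the list alone and 3 and 7 under poly-A spike-in scaling, with PTPN6 at 0.42 and CD72 at 0.37. Among 24 p53 targets 7 rose and 2 fell, or 9 and 3 adjusted over the list alone, with TP53INP1 at 0.52 and ZMAT3 at 0.50. In the interferon and double-stranded RNA list, IFIH1 rose by 0.55 and PARP14 by 0.21, and 30 of 32 genes did not pass. Both groups received siRNA, so a response to siRNA as such would not show as a difference here. PARP14 was lost under each other scaling (limma adjusted p = 0.0867 after quantile normalization, 0.0766 with equal medians, 0.0710 after cyclic loess and 0.378 with poly-A spike-ins). HSPB1 fell by 0.56 and EGR1 rose by 0.43 among 21 heat shock and immediate early genes, of which 2 rose and 1 fell, or 5 and 3 adjusted over the list alone. Of 24 hypoxia and glycolysis genes 4 rose and 2 fell, or 6 and 7 adjusted over the list alone. With poly-A spike-in scaling 0 hypoxia genes rose and 10 fell, against 2 and 9 heat shock, 3 and 5 p53 and 1 and 5 interferon genes. NOTCH2 rose by 0.42 in the Notch list, ELL2 rose by 0.49 in the plasma cell list and UQCRC1 fell by 0.25 in the oxidative phosphorylation list, each alone in its list. Adjusted over the list alone UQCRC1 did not pass (adjusted p = 0.0705), and 2 plasma cell genes rose and 1 fell. Under poly-A spike-in scaling 10 oxidative phosphorylation genes fell and 0 rose, and in the plasma cell and Notch lists 4 fell and 1 rose. Among 15 genes of the small RNA machinery none passed over all probe sets, and AGO2 at -0.21 and TNRC6A at 0.19 passed adjusted over the list alone (adjusted p = 0.0464 for each), while 3 fell under poly-A spike-in scaling.

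Markers of other cell types were not called as groups by camera. ZAP70, NCAM1 and CD247 fell by 0.35, 0.25 and 0.22 among 19 T and NK cell markers. ELF3 rose by 0.22 among 15 epithelial markers, but passed under none of the 4 other scalings (limma adjusted p = 0.0746 after quantile normalization, 0.0585 with equal medians, 0.0583 after cyclic loess and 0.309 with poly-A spike-ins). No monocyte, fibroblast or erythroid marker passed, with CD163 at -0.12, SPARC at 0.23 and HBD at 0.18. Under poly-A spike-in scaling, with its shift of every probe set, 4 monocyte and 3 fibroblast markers fell.

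Several control measures also differed between the LEF1 siRNA and scrambled siRNA arrays. The difference between the 3' and 5' probe sets of ACTB, a sign of RNA integrity, was 0.23 ± 0.06 with LEF1 siRNA and 0.05 ± 0.07 with scrambled siRNA. It was higher by 0.11, 0.33 and 0.12 in batches 1, 2 and 3 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The same p was reached by ACTB 3' minus middle, higher by 0.18, by ISGF3A 3' minus 5', higher by 0.22, and by GAPDH 3' minus middle, higher by 0.05. The 3' minus 5' difference of GAPDH changed by 0.00031. The poly-A spike-ins were higher with LEF1 siRNA by 0.14, 0.10 and 0.18 in the 3 batches (exact permutation p = 0.5 over the 6 arrays, and 0.25 over the 3 batch differences, the smallest these allow).

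Without block, camera called 9 lists, and no list was called with an estimated correlation, or by the directional test of fry, in either fit. The mixed test of fry, which asks for change in either direction, called 19 of 29 lists with batch as block and 12 without. It gives a list no direction. With batch as block it called the Wnt target and Wnt component lists (fry mixed adjusted p = 0.0261 and 0.0447), among other lists that camera did not call. Without block these 2 Wnt lists did not pass it (0.284 and 0.241). No member of any list passed without block at the probe set used for its list, against 5 G2/M and 11 antigen presentation genes when adjusted over the list alone.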

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

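The tests of normalization, spike-ins, level, RNA quality, other cell types and background were chosen after the results were seen. The splits of the arrays were planned, as was quantile normalization as an alternative, though not as a test of the excess below.

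Signal in the control probe sets, which took no part in the comparison, was higher with LEF1 siRNA at 6 of 62. These passed a limma adjusted p of 0.05 with batch as block. Of all tested probe sets 6.09% passed in that fit, in either direction. The 62 hold several probe sets per transcript. The 5' probe set of the 28S ribosomal RNA control was higher by 0.46. The dap spike-in was higher by 0.33 at its 3' and 0.24 at its middle probe set. The hybridization controls BioDn-5 and BioC-3 were higher by 0.31 and 0.23, and the 3' probe set of the ISGF3A control by 0.22. Other probe sets of the same transcripts did not pass. Among them 28S differed by 0.06 at its middle and 0.02 at its 3' probe set, r2-Ec-bioD-5 by 0.11, r2-Ec-bioC-3 by 0.07 and ISGF3A 5' by -0.002. Of all 62, 51 were above 0, while all ACTB and GAPDH probe sets were below 0.

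The first pattern is the excess of higher calls, 75.2% with batch as block. After quantile normalization 56.1% of calls were higher, but 66.4% with equal medians, so part of the excess may come from how the arrays were normalized. The poly-A spike-ins were higher by 0.14 with LEF1 siRNA, which could reflect less cellular RNA per spike-in. The hybridization spike-ins, added after labelling, were higher too in batches 1 and 2, so the spike-ins leave this open. An effect of LEF1 siRNA on more genes in one direction was not tested.

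The second pattern is the fall of many cell division genes beside the rise of some antigen presentation genes, with batch as block. Camera called these lists only at the preset correlation, and the directional test of fry called none of them. A difference between arrays that depends on level is argued against: the G2/M list's mean change of -0.21 lay at percentile 0 of 10000 random lists matched on level, and the antigen presentation list at percentile 100. The samples were cultures of an established lymphoma line, so monocytes or macrophages were not part of the design. RNA from these cells was not detected, but the markers alone cannot exclude it. Their markers changed by 0.0035 on average against 0.20 for the antigen presentation list, yet lie near the floor at a median of 6.62, with LYZ at 6.39 and CD14 at 6.66. RNA quality stays open, because 3' minus 5' differences were higher by 0.19 for ACTB and 0.22 for ISGF3A, while for GAPDH 3' minus 5' showed none and 3' minus middle was higher by 0.05. An effect of LEF1 siRNA, or of its pool on other transcripts, also stays open and cannot be separated by a design with 1 pool.

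The third pattern is the smaller fall of LEF1 at its dimmest probe set. If the true fall equalled that of the brightest one, a background of 7.23 on the log2 scale would be needed. A background shared by all probe sets is argued against, since the LEF1 probe set of middle brightness read 6.61 ± 0.09 with LEF1 siRNA. That background also lies at percentile 61.3 of all probe set means. A background of this probe set alone was not tested and stays open. Transcript forms that differ in siRNA sensitivity were not tested, since probe positions were not used here.

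Without block the 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 10 probe sets, the other splits at most 0, and so 1 split reached the real count. With batch as block there are 4 ways to exchange groups within batches, again too few. The real grouping gave 3328 probe sets, the others at most 0, and so 1 grouping reached the real count.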

How the results depend on the processing

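Cyclic loess and poly-A spike-in scaling were chosen after the data were seen. With the replicate block, which is batch here, the 10 calls without block became 3328, and with batch as a random block they became 932. The dimmest LEF1 probe set, at -0.29 in each of these, then passed the threshold. Without block the count was 23 after quantile normalization, 23 after cyclic loess, 11 under poly-A spike-in scaling with 3 of the 10 among them, 5 with 1 probe set per gene, 6 with trend and robust eBayes, 39 with array weights and 63 at an adjusted p of 0.1. Leaving out arrays or batches gave from 0 to 8 calls without block, against 4280 probe sets at an unadjusted p under 0.05 with all arrays. LEF1 differences there ran from -1.94 to -1.75 at the probe set of middle brightness and from -2.94 to -2.51 at the brightest. The former lost the threshold without batch 1, batch 2 or LEF1 siRNA replicate 2, as the latter did without these and others. With batch as block the count was 1949 with 1 probe set per gene, 81 at 1.5-fold or more and 13508 under poly-A spike-in scaling, and from 1407 without batch 2 to 3880 without batch 1. The count of called lists went to 0 with an estimated correlation and 0 with the directional test of fry, in both fits. The estimated correlation uses only the residual degrees of freedom. The ribosomal protein list turned from -0.029 to 0.046 under quantile normalization, 0.039 with the most variable probe set per gene and 0.043 under cyclic loess, in both fits, and ran from -0.080 without batch 1 to 0.048 without batch 3. The cause of these shifts was not tested. With batch as block, all 244 alternatives for named genes and all 31 for LEF1 kept direction and side of the threshold, while 38 of 143 for called lists lost it and 4 reversed. The named genes were picked in these data for large changes past the threshold, so their stability does not speak for the other calls. Without block, 67 of 130 alternatives for named genes lost the threshold, as did 23 of 108 for called lists, with 4 reversed. Correlations of the batch differences across probe sets rose from 0.426, 0.339 and 0.448 to 0.520, 0.430 and 0.584 without dim probe sets. A pseudocount was not run, since the values are log2. Dim probe sets near background limit what small changes can be seen.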

Other observations

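All tests of gene families here were chosen after the genes that prompted them were seen, and all are hypotheses. A first run included the prompting genes, and the values given leave them out. Replication-dependent histone genes, prompted by H2BC12 and H2AC6, were not called as a family, which leaves a rise open. The other 40 had a mean change of 0.020 and a median of -0.0058, 19 of them above 0 and 21 below. The threshold was passed by 3, all higher, among them H2BC5 at 0.41. Against other genes camera gave the direction as lower, without a call (camera adjusted p = 0.515 with batch as block). Of these 40, 24 lay below the median level of all probe sets, where changes are compressed. Cytosolic aminoacyl-tRNA synthetase genes, which load amino acids onto tRNAs and were prompted by EPRS1 beside the falls of PSAT1 and ATF5, may be lower as a family. Their mean change was -0.090 over 14 genes, with a median of -0.042, 7 above 0 and 7 below, of which 3 fell and 0 rose (the family took symbols ending in ARS1 and EPRS1, so TARS3, which rose, was not in it; camera adjusted p = 0.00205; adjusted p = 0.264 with an estimated correlation). GARS1 fell by 0.31, SARS1 by 0.30 and TARS1 by 0.24.

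FCRL3, an Fc receptor-like gene of B cells, rose by 0.69. The other 6 genes of its family had a mean change of 0.12 and 1 of them rose, FCRLB, by 0.33. With batch as block the family passed with FCRL3 included (camera adjusted p = 0.00355; adjusted p = 0.200 with an estimated correlation) and not without it (camera adjusted p = 0.078; adjusted p = 0.448 with an estimated correlation), so that call rested on the gene that prompted it. In the fit without block it passed without FCRL3 at the preset correlation (camera adjusted p = 0.0491). An estimated correlation was not run for that fit. Zinc finger genes named ZNF, prompted by ZNF721, may be higher by a small amount. Their mean change was 0.070 over 424 genes, 48 higher and 2 lower (camera adjusted p = 0.00359; adjusted p = 0.315 with an estimated correlation). Under poly-A spike-in scaling the mean changes turned to -0.02 for the Fc receptor-like genes, -0.07 for the ZNF genes and -0.12 for the histone genes.

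AXIN2, a feedback target of Wnt signalling that was chosen after its values were seen, differed by 0.08, from 7.16 with scrambled siRNA to 7.24 with LEF1 siRNA, and did not pass (limma adjusted p = 0.573 with batch as block). Both levels lie near the median of 6.91 of all probe sets, where changes are compressed, so a change is not excluded.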
